A study of Mus musculus with 12 samples.

How the data were processed

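RNA was sequenced from whole lungs of adult C57BL/6 mice and from extracellular vesicles in the culture medium of lung mesenchymal cells, collected over 48 hours of culture per the labels' protocols. The 12 libraries fell into 4 groups by their titles: 2 mutant-labelled lung libraries, 4 wild-type lung libraries, 2 mutant-labelled vesicle libraries and 4 wild-type vesicle libraries. RNA was extracted with Trizol and libraries followed a standard Illumina preparation, per the labels' protocols. Alignment to the mouse build mm9 used TopHat2 and counting used HTSeq, per the submitters' processing notes. Their versions and settings, the strand setting and the gene annotation are not given in the sources used here.

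The authors deposited 1 table of lungs and 1 of vesicles, each with 6 columns that their sample descriptions tie to libraries and 0 other value columns. The deposited values were read as RPKM (reads per kilobase of exon and per M, or megaread, counted in genes). The table headers name no unit, so this was read from the values. Multiplied by annotated exon length, 52.9% to 56.5% of a library's values above 0 fell close to whole multiples of a single step per column. The other values were taken to have the same unit. Reads and read pairs could not be told apart, so RPKM here stands for either. The lung table listed 21950 genes, of which 2726 were at 0 in every library. The vesicle table listed 8096 genes, and in each of them the larger of the 2 group means was at least 2.003 RPKM. Whether every gene missing from the vesicle table lay below such a level could not be checked, so such genes are called not listed, and no level is read from that. Spreadsheet dates in place of 27 gene symbols in the lung table and 15 in the vesicle table were turned back into symbols by their Ensembl identifiers. Coordinates are those of GENCODE M1 on mm9. An exon length from that annotation was at hand for 20462 of the 21950 lung genes and 7906 of the 8096 vesicle genes.

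Depth was worked out from the step of each column. The lung libraries held 42.7 to 44.8 M reads in genes, so that 1 read per kilobase was worth 0.0223 to 0.0234 RPKM. The mutant-labelled vesicle libraries held 1.75 and 1.68 M reads and the wild-type vesicle libraries 4.2 to 5.41 M, where 1 read per kilobase was worth 0.185 to 0.596 RPKM. Reads per gene were recovered for 99.9% of the genes above 0 in each table, counting a value as whole within 0.02 of an integer. The annotated length served for 9561 of 19224 lung genes and 3676 of 8096 vesicle genes, and for the rest a length between 150 and 30000 bases that gave whole reads was taken, the nearest to the annotated one or, without one, the shortest. The recovered reads summed to 98.7% to 100.9% of the expected totals and are approximate. They were used to give depth and reads per gene, to compare replicates of a group, and to thin libraries to equal depth. The simulated data and 1 alternative test also used them.

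Mutant-labelled and wild-type libraries were compared within each table with limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1). Genes with at least 1 RPKM in at least 2 libraries were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. SE and 95% confidence intervals are limma's moderated ones. The plan, fixed before the data were examined, named a count test for counts and this test for normalized values. The count tests were not run, because the values were RPKM. For the same reason vesicles and lung, normalized in separate tables, were compared by ranks within each library without a test, and the difference between the genotype effects in lung and vesicles was not tested.

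Before the data were examined, 40 gene lists were fixed for cell types, pathways and transcript classes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with an estimated correlation and with fry. A list score is the mean over its tested members of log2(RPKM + 1) after subtraction of each gene's mean over the 6 libraries. Scores were compared by a two-sided exact permutation test over the 15 ways to draw 2 of 6 libraries, whose smallest possible p is 0.0667. The rule for named genes took Tbx4, Ghr, Col1a1 and Col1a2, then the 8 genes with the smallest p in a direction where fewer than 5 passed, and the members with the smallest p of each list, up to 4 where camera called it and up to 2 elsewhere. For vesicles against lung it took the 12 genes that gained and the 12 that lost most, at a mean log2 level of at least 5, and up to 4 members of each list. Because the values were RPKM, its expression limit was applied to mean log2(RPKM + 1) in place of log2 CPM, and for vesicles against lung it ranked genes by the change in percentile. A gene outside this rule is said to have been chosen after its values were seen. The text names part of the genes that the rule took, and 1 of the lower lung genes with the smallest p is not reported here.

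Alternatives planned in advance were a pseudocount of 0.1, no filter, a filter at 5 RPKM, leaving out haemoglobin, immunoglobulin, mitochondrial and Y-linked genes, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were sex as a covariate, the erythroid list score as a covariate in lung, the wild-type libraries without Y-linked transcripts alone, median-ratio scaling, limma-voom on the recovered reads, array weights and thinning to equal depth. With 1 mutant-labelled library left, limma takes the spread from the wild-type libraries and assumes that the lone library varies as they do. In those fits the filter was held at 2 libraries after a first run, in which it had fallen to 1 library with the smaller group; the values with 1 library are given too. The rule that decides when a list median counts as excluding an explanation, and the pattern that leaves out immunoglobulin and T cell receptor segments, were also tightened after a first run. Replicates of a group differed by a chi-square of at least 21.26 per degree of freedom over genes, so no library was counted as a copy of another. The labels do not say that replicates are separate animals or cultures, so p-values measure only the spread between these samples, part of which may be technical. Y-linked transcripts were present in wild-type replicates 1 and 2 and near 0 in 3 and 4. The wild-type libraries of a source thus did not all come from a single animal. Libraries alike in these transcripts may still share an animal.

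The procedure was tested on simulated data with 200 changed genes. The spread of each gene was taken from the wild-type libraries alone, although the mutant-labelled pairs agreed less well. The shares called may therefore be too high. In the simulation of the lung libraries (13660 genes) limma called 85.1%, 98.5% and 100% of genes changed 2-fold, 4-fold and 8-fold, and 17 unchanged genes. In that of the vesicle libraries (7782 genes) it called 0%, 3% and 9.7%, and 1 unchanged gene. For a simulated list of 14 genes changed 2-fold the camera p was 3.75e-36 in lung and 4.51e-06 in vesicles, and for an unchanged list it was 0.385 and 0.443. The simulated genes were drawn independently of each other, while the lung neutrophil and vesicle macrophage lists had estimated correlations of 0.456 and 0.637. These p-values therefore do not show how camera with a preset correlation treats correlated lists. Recovery, tables and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.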

Results

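RNA was measured by sequencing in whole lungs of adult C57BL/6 mice and in extracellular vesicles, membrane particles that cells release, from cultured lung mesenchymal cells. Each source held 2 libraries labelled mutant and 4 labelled wild type, 12 libraries in all. The sample labels give the mutant genotype as ColcreER with floxed Tbx4, a T-box transcription factor of lung mesenchyme. CreER is a Cre recombinase switched on by tamoxifen, here with a Col driver. The design text of the series names Tbx4creER, with Tbx4 as the driver, and floxed Ghr, the growth hormone receptor. Under that text Tbx4 would not be the floxed gene. The libraries are therefore called mutant-labelled throughout, and differences are given as mutant-labelled minus wild type. The comparisons were mutant-labelled against wild type in lung, the same in vesicles, and wild-type vesicles beside wild-type lung. Lung libraries held 42.7 to 44.8 M reads in genes (M, megareads). The mutant-labelled vesicle libraries held 1.75 and 1.68 M reads, and the wild-type vesicle libraries 4.2 to 5.41 M. Errors are SD over 2 mutant-labelled or 4 wild-type libraries unless named otherwise.

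Neither gene named as the target was lower in both mutant-labelled lungs than in all wild-type lungs. Tbx4 (ENSMUSG00000000094, mm9 chromosome 11, 85699924 to 85729599) stood at 20.9 and 36.8 RPKM in mutant-labelled lungs 1 and 2. The wild-type lungs stood at 29.7, 26.1, 29.0 and 30.1 RPKM. Mutant-labelled library 1 thus lay below and library 2 above every wild-type lung, so library 2 showed no fall of Tbx4 in whole lung. The means were 28.8 ± 11.2 and 28.7 ± 1.82 RPKM, with a log2 difference of -0.04 (SE 0.20, 95% confidence interval -0.54 to 0.45, limma adjusted p = 0.996). It was 0.35 without mutant-labelled lung 1 and -0.44 without mutant-labelled lung 2. These values rest on 3115 to 5395 reads per library and cover the whole gene, while the labels do not say which exons are floxed. Whole-lung reads also do not show whether Tbx4 was deleted in part of the cells. The alveolar fibroblast list, which does not hold Tbx4, had scores on the same sides of wild type (-0.379 and 0.231 against -0.077 to 0.124). In vesicles Tbx4 was not listed. Ghr (ENSMUSG00000055737, chromosome 15, 3267760 to 3533492) stood at 9.84 and 12.9 RPKM in mutant-labelled lungs against 13.4, 12.7, 11.9 and 12.9 RPKM, a difference of -0.16 (SE 0.11, interval -0.42 to 0.10, adjusted p = 0.994). In vesicles Ghr stood at 13.1 and 11.2 RPKM against 21.3, 19.8, 23.6 and 25.1 RPKM. Both mutant-labelled vesicle values lay below all wild-type ones, but the difference of -0.83 (SE 0.66, interval -2.26 to 0.59) did not pass the test (adjusted p = 0.627). It rests on 206 and 168 reads against 829 to 1218. The collagen I genes Col1a1 and Col1a2 were taken as possible sources of the Col driver. They differed in lung by -0.08 (SE 0.13) and -0.01 (SE 0.13), and in vesicles by 0.13 (SE 0.67) and 0.26 (SE 0.78).

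**Figure D1:**
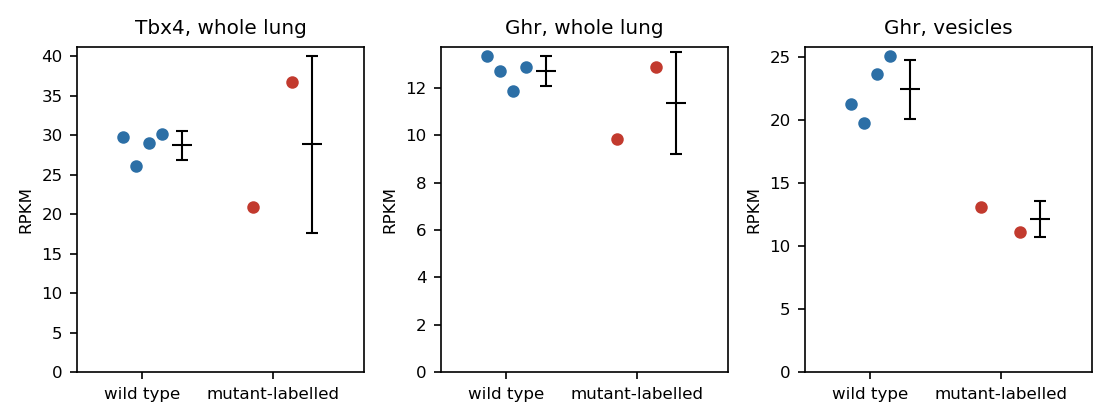
RPKM of Tbx4 in lung and of Ghr in lung and vesicles, with 1 dot per library and the mean ± SD of each group beside the dots (2 mutant-labelled and 4 wild-type libraries). Tbx4 in the mutant-labelled lungs lies on either side of the wild-type lungs (20.9 and 36.8 against 26.1 to 30.1 RPKM), and Ghr in the mutant-labelled vesicles lies below the wild-type ones (13.1 and 11.2 against 19.8 to 25.1 RPKM).

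Sex differed between the groups. The Y-linked genes Ddx3y (20.6 and 19.9 RPKM) and Eif2s3y (15.4 and 15.7 RPKM) were read in wild-type lungs 1 and 2, and at or near 0 in the other lungs. The same replicate numbers carried them in vesicles, with Ddx3y at 24.4 and 10.9 RPKM and Eif2s3y at 52.6 and 35.2 RPKM. No mutant-labelled library held them at a comparable level.

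In the lung comparison neutrophil genes rose together in both mutant-labelled libraries by camera with a preset correlation, with a median log2 difference of 1.54, and transcripts of ribosomal proteins (0.12) and immediate early genes (0.30) rose as lists. These calls were lost with an estimated correlation (adjusted p = 0.760, 0.963 and 0.781), and the immediate early call also ended without mutant-labelled lung 1 (adjusted p = 0.0645). Genes of heart muscle (-0.42), mitochondrial DNA (-0.18) and the extracellular matrix (-0.14) fell as lists by the same test. With an estimated correlation each of these had an adjusted p = 0.963, and the matrix median was 0.10 without mutant-labelled lung 1 and the mitochondrial median 0.03 without mutant-labelled lung 2. No single gene passed. Of 13701 genes tested, limma-trend called 0 at the threshold (smallest adjusted p = 0.364), and limma-voom on recovered reads also called 0. At an unadjusted p under 0.05 limma-trend took 514 genes, 348 higher and 166 lower, where 685 are due by chance, and limma-voom took 496. Of these 514 genes 67.7% were higher. Of the genes at an unadjusted p under 0.05 after median-ratio scaling, 56.8% were higher. The 2 groups did not overlap for 1027 genes that were higher and 565 that were lower, together 11.6% of genes against 13.3% by chance. The 514 became 1349 without mutant-labelled lung 1, 2468 without mutant-labelled lung 2 and 332 without wild-type lung 4. The median SE was 0.091. Across genes, wild-type lungs correlated at 0.98 to 0.99 (Spearman) and the mutant-labelled pair at 0.965. Camera called 12 of 38 gene lists, 6 higher and 6 lower, while an estimated correlation called 0 (smallest adjusted p = 0.760) and fry 0 (smallest adjusted p = 0.217).

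The neutrophil list had the smallest p. All 14 tested members had a log2 difference above 0, with a median of 1.54 (camera adjusted p = 7.58e-19). With an estimated correlation its adjusted p = 0.760. Adjusted over the list alone 11 of the 14 members passed and over all genes 0, and in 11 the groups did not overlap, where chance gives 13.3%. That chance holds for a single gene. Members varied together (estimated correlation 0.456) and can separate together, so this count and those of other lists are no test. Retnlg, a resistin-like protein of neutrophils (ENSMUSG00000022651, chromosome 16, 48872721 to 48874611), stood at 50.8 ± 14.5 RPKM against 12.3 ± 2.43 (1.95, SE 0.22). Ly6g, the surface antigen of mouse neutrophils (ENSMUSG00000022582, chromosome 15, 74987123 to 74989169), stood at 2.94 ± 1.13 RPKM against 0.292 ± 0.0881 (1.58, SE 0.17), on 88 and 152 reads against 9 to 17. S100a8, a calcium-binding protein of granulocytes, stood at 154 ± 75.3 RPKM against 35.5 ± 11.1 (2.05, SE 0.37), and the collagenase Mmp8 at 7.10 ± 2.99 against 1.81 ± 0.559. The list scores were 0.73 and 1.262 in the mutant-labelled lungs and -0.628, -0.531, 0.025 and -0.858 in the wild-type lungs. That order has a two-sided exact permutation p of 0.0667, the smallest that 15 splits allow. The ribosomal protein, immediate early and cell cycle lists reached the same p in lung. The other lung lists that camera called had an exact permutation p of 0.2 (senescence) to 0.733 (alveolar fibroblasts), with 0.333 for heart muscle. The erythroid score, a measure of blood, was -0.166 and 0.783 in the mutant-labelled lungs against -0.738, -0.493, 0.771 and -0.159.

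**Figure D2:**
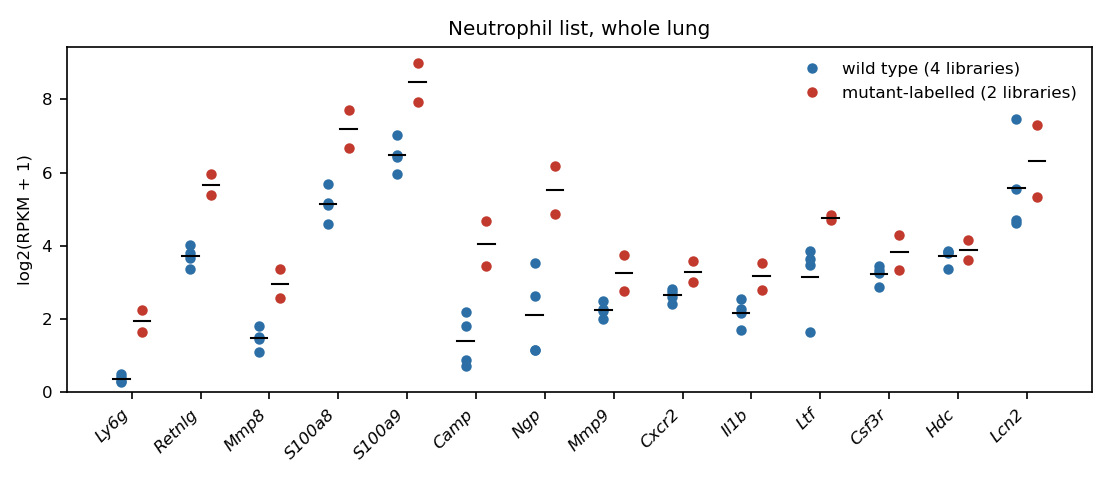
Expression of neutrophil genes as log2(RPKM + 1) in whole lung, with 1 dot per library and a line at the mean of 2 mutant-labelled or 4 wild-type libraries. In 11 of the 14 genes both mutant-labelled libraries lie above all wild-type ones (not in Lcn2, Hdc and Csf3r), as in Retnlg (50.8 against 12.3 RPKM) and Ly6g (2.94 against 0.292 RPKM).

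Cytosolic ribosomal protein transcripts rose by little and together. All 73 tested members had a difference above 0, with a median of 0.12 (camera adjusted p = 3.26e-17), and an estimated correlation gave an adjusted p = 0.963. The groups did not overlap in 54 of the 73, where chance gives 13.3% for a single gene, and adjusted over the list alone 0 passed. With an estimated correlation of 0.674 the members can separate together. Rpl18 stood at 91.5 RPKM against 80.4 (0.18, but 0.11 without mutant-labelled lung 1 and 0.26 without mutant-labelled lung 2) and Rps20 at 96.7 against 86.7 (0.16). Immediate early genes, which cells switch on within minutes of a stimulus, had a median of 0.30 and 13 of 18 members above 0 (camera adjusted p = 4.27e-05). Its adjusted p = 0.781 with an estimated correlation, and 4 members passed adjusted over the list alone. Among them the transcription factor Klf2 stood at 142 RPKM against 76.9 (0.88), the phosphatase gene Dusp1 at 61.5 against 37.9 (0.69) and the antiproliferative gene Btg2 at 74.3 against 44.8 (0.71). Fos was uneven, at 26.0 and 7.20 RPKM against 3.10 to 4.57. Without mutant-labelled lung 1 the call of the immediate early list ended (adjusted p = 0.0645, median 0.19).

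The remaining 3 lists that rose depended on single libraries. Cell cycle genes had a median of 0.12 with 14 of 16 above 0 (camera adjusted p = 0.00318, and adjusted p = 0.781 with an estimated correlation). The kinase gene Cdk1 stood at 1.10 RPKM against 0.766 and the anaphase activator Cdc20 at 2.84 against 2.30. Without mutant-labelled lung 2 their list had an adjusted p = 0.457 and a median of 0.05. The senescence list had a median of 0.16 with 11 of 13 above 0 (camera adjusted p = 0.0326, and adjusted p = 0.963 with an estimated correlation). Its members with the smallest p were the chemokine Cxcl12, at 52.4 RPKM against 37.5, and the lamin gene Lmnb1, at 8.84 against 7.41. That call ended without mutant-labelled lung 1 (adjusted p = 0.606), wild-type lung 2 (0.0601) or wild-type lung 4 (0.0829), and at a filter of 5 RPKM (0.0794), and the median was 0.27 without mutant-labelled lung 2. Interferon-response genes had a median of 0.14 with 15 of 18 above 0 (camera adjusted p = 0.0497, and adjusted p = 0.963 with an estimated correlation). The chemokine Cxcl10 stood at 1.58 RPKM against 0.877 and Rtp4 at 13.5 against 10.5. Without mutant-labelled lung 2 their median turned to -0.08. The camera call ended without wild-type lung 1 (adjusted p = 0.119), wild-type lung 3 (0.425) or wild-type lung 4 (0.0707), and with the replicate number as a block. It also ended with array weights (0.0573), with the erythroid score as a covariate (0.0633), at equal depth (0.0520) and at a filter of 5 RPKM (0.0909). The interferon median was 0.33 without mutant-labelled lung 1 and 0.27 without wild-type lung 2. With the erythroid score as a covariate the cell cycle median was 0.08 and the senescence median 0.10, both still called. Adjusted over the list alone, 0 members passed in each of these 3 lists.

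Heart muscle genes fell in the mutant-labelled lungs, with a median of -0.42 and 1 of 15 above 0 (camera adjusted p = 6.47e-09). With an estimated correlation the adjusted p = 0.963, and in 4 of the 15 the groups did not overlap, where chance gives 13.3%. The heavy chain Myh6 stood at 94.96 RPKM against 144 (-0.58), the calcium channel Ryr2 at 3.21 against 5.32 (-0.57) and the actinin Actn2 at 9.58 against 14.4 (-0.51). The scores were -0.239 and -0.295 in the mutant-labelled lungs and 0.428, 0.35, -0.367 and 0.123 in the wild-type lungs, so that wild-type lung 3 was the lowest. The heart muscle median was -0.16 with sex and -0.20 with the erythroid score as a covariate. The genes of mitochondrial DNA had a median of -0.18 and 0 of 13 above 0 (camera adjusted p = 5.47e-04, and adjusted p = 0.963 with an estimated correlation), with mt-Nd1 at 3731 RPKM against 4524 and mt-Nd5 at 1865 against 2243. Without mutant-labelled lung 2 that median was 0.03 and the call ended (adjusted p = 0.825), as it did with sex (0.114, median -0.10) or the erythroid score (0.264, median -0.04) as a covariate. It was -0.41 without mutant-labelled lung 1, -0.12 without wild-type lung 1 and -0.28 without wild-type lung 3. Adjusted over the list alone 0 members of either list passed.

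Lists of lung structural cells fell by less. Extracellular matrix genes had a median of -0.14 and 5 of 26 above 0 (camera adjusted p = 0.00107, and adjusted p = 0.963 with an estimated correlation), with the fibulin Fbln1 at 13.8 RPKM against 16.1 and thrombospondin 1 (Thbs1) at 39.8 against 47.4. Genes of alveolar type 1 cells, which form the gas exchange surface, had a median of -0.15 and 3 of 16 above 0 (camera adjusted p = 0.00428, and adjusted p = 0.963 with an estimated correlation), with Spock2 at 96.4 RPKM against 111 and Gprc5a at 285 against 319. Smooth muscle genes had a median of -0.10 and 0 of 14 above 0 (camera adjusted p = 0.0125, and adjusted p = 0.963 with an estimated correlation), with Acta2 at 156 RPKM against 186 and Des at 62.1 against 72.7. Alveolar fibroblast genes had a median of -0.10 and 3 of 16 above 0 (camera adjusted p = 0.0497, and adjusted p = 0.963 with an estimated correlation). Their marker Pdgfra stood at 21.2 and 40.8 RPKM against 33.8 to 42.4. Adjusted over the list alone 0 members of these 4 lists passed.

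Mutant-labelled lung 1 carried much of these falls. Without it the matrix median was 0.10 (adjusted p = 0.240), the type 1 cell median 0.08 (0.174), and the alveolar fibroblast list was called in the other direction (median 0.19, adjusted p = 0.0290). Its scores were -0.256 for matrix, -0.295 for type 1 cells and -0.379 for alveolar fibroblasts, beside 0.894 for club cells and 0.695 for ciliated cells of the airways. Retnla, a secreted protein of type 2 inflammation, stood at 747 RPKM in it against 84.5 in mutant-labelled lung 2 and 30 to 87.9 in wild-type lungs. Scgb3a1, an airway secretoglobin, stood at 285 RPKM against 89.3 and 2.12 to 123. Without mutant-labelled lung 2 the matrix median was -0.32, the type 1 cell median -0.35 and the alveolar fibroblast median -0.54. The matrix median was -0.07 with sex as a covariate. The type 1 cell call also ended without wild-type lung 1 (0.0539) and with sex as a covariate (0.151), which ended the senescence call (0.151) and the alveolar fibroblast call (0.0751) too. The alveolar fibroblast call ended without wild-type lung 1 (0.127), wild-type lung 3 (0.1002) or wild-type lung 4 (0.0849), and its median was -0.17 without wild-type lung 2 and -0.21 with the erythroid score as a covariate. The alveolar fibroblast call also ended with the replicate number as a block, with median-ratio scaling (0.0807), at equal depth (0.0520), without a filter (0.0662) and at a filter of 5 RPKM (0.0680). The smooth muscle call ended without mutant-labelled lung 2 (0.641) or wild-type lung 4 (0.195) and with the erythroid score as a covariate (0.191), and its median was -0.19 without mutant-labelled lung 1 and -0.18 without wild-type lung 1.

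Other cell types of the lung did not pass by camera. The list of ciliated cells had all 17 members above 0 (adjusted p = 0.0597), and adjusted p was 0.0733 for alveolar type 2 cells, 0.109 for B cells, 0.115 for macrophages and 0.134 for T and natural killer cells. Endothelium (0.692), pericytes (0.746) and T-box and lung mesenchyme transcription factors (0.857) did not pass either. Growth hormone and IGF signalling, the pathway of Ghr, had an adjusted p of 0.431. In 8 of the lung lists without a call and 4 of the vesicle lists without a call, the median, the mean and the test differed in sign. Among genes outside the called lists, the smallest p belonged to the transcriptional repressor Hic1, at 9.32 RPKM against 6.40 (0.48), the flippase gene Atp9a at 18.5 against 13.0 (0.48) and the antibacterial Pglyrp1 at 30.4 against 18.0 (0.73). Uba6 (4.05 against 2.49 RPKM), RP23-326D6.5 (43.0 against 31.2), S100a4 (56.0 against 40.2) and Plk2 (26.2 against 16.8) followed. The lower genes with the smallest p were Cmya5 (2.11 against 3.08 RPKM), Tomm34 (11.3 against 14.01), Esm1 (14.9 against 21.0), Fblim1 (15.1 against 18.8), Muc6 (0.837 against 1.43), Serpina3f (4.87 against 7.42) and Angptl6 (3.46 against 4.41). None of these passed.

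In the vesicle comparison macrophage genes rose in the mutant-labelled libraries by camera with a preset correlation, with a median of 2.44, while transcripts of ribosomal proteins (-0.42), histones (-1.12) and smooth muscle (-1.45) fell as lists. These calls were lost with an estimated correlation (adjusted p = 0.701, 0.926, 0.701 and 0.701), and the falls ended without mutant-labelled library 1 (medians -0.03, -0.20 and 0.16). No single gene passed by limma-trend. Of 7615 genes tested it called 0 (smallest adjusted p = 0.229) and took 781 at an unadjusted p under 0.05, 398 higher and 383 lower, where 381 are due by chance. Limma-voom on recovered reads called 1 gene, the protocadherin Fat4 (76.4 against 4.82 RPKM, 4.23 by voom, adjusted p = 0.0187; adjusted p = 0.359 by limma-trend), and took 627 unadjusted. The share of higher genes among those with an unadjusted p under 0.05 was 51.0%, but 37.5% with a pseudocount of 0.1 and 85.3% by voom. The groups did not overlap for 752 higher and 757 lower genes, 19.8% against 13.3% by chance. The vesicle libraries varied far more than the lungs, with a median SE of 0.989 and a median difference over all genes of -0.14. Wild-type vesicle libraries correlated at 0.589 to 0.678 across genes and the mutant-labelled pair at 0.417. Mutant-labelled vesicle library 1 correlated with the wild-type ones at 0.356 to 0.43 and library 2 at 0.564 to 0.603. Without library 2, limma called 377 genes, 87 higher and 290 lower, with the lone library 1 assumed to vary as the wild-type ones do. When genes read in only 1 library were tested as well it called 371, 206 higher and 165 lower, so the balance of directions turned with the filter. The 781 became 440 without mutant-labelled library 1, 1758 without library 2 and 515 without wild-type library 1. Camera called 4 of 23 lists, while an estimated correlation called 0 (smallest adjusted p = 0.701) and fry 0 (smallest adjusted p = 0.448).

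All 9 tested macrophage and monocyte genes had a difference above 0, with a median of 2.44 (camera adjusted p = 2.09e-04). With an estimated correlation the adjusted p = 0.701, and adjusted over the list alone 0 members passed. In 4 of the 9 the groups did not overlap, where chance gives 13.3% for a single gene and 19.8% of all vesicle genes did so. C1qc, a complement subunit made by macrophages, stood at 49.8 and 22.9 RPKM against 0, 9.66, 4.93 and 0 (3.63, SE 1.14). The lysosomal glycoprotein Cd68 stood at 275 and 203 RPKM against 0.178 to 105, and the lysozyme Lyz2 at 4369 and 3191 against 140, 2415, 1977 and 20.6. The integrin Itgax stood at 10.9 and 1.18 RPKM and at 0 to 0.0552 in wild type. C1qc and Lyz2 were thus higher in wild-type vesicle libraries 2 and 3 than in libraries 1 and 4. The list scores were 1.94 and 1.396 against -2.631, 0.783, 1.119 and -2.608 (two-sided exact permutation p = 0.133). The median was 4.10 with a pseudocount of 0.1 and 4.23 by voom. Without mutant-labelled library 1 the median was 2.57 with 8 of 8 above 0 (adjusted p = 0.0229). When genes read in only 1 library were tested as well it was 2.28 with 9 of 9 above 0, and the call was lost (adjusted p = 0.0981) at a median close to that of all libraries.

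**Figure D3:**
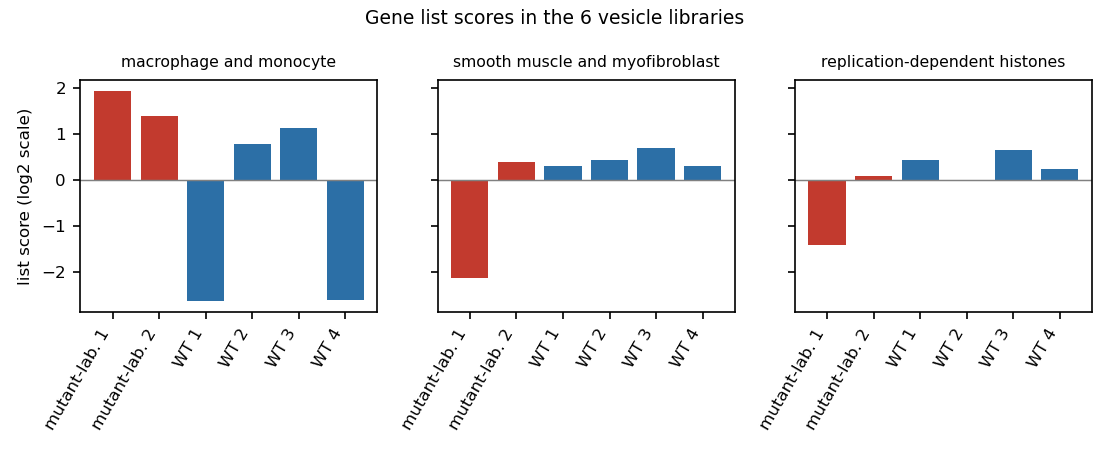
List scores of the 6 vesicle libraries, with 1 bar per library from 0, where a score is the mean over the tested genes of a list of log2(RPKM + 1) after centring each gene. The macrophage scores of the mutant-labelled libraries are 1.94 and 1.396 and those of wild type spread from -2.631 to 1.119, while the low smooth muscle (-2.132) and histone (-1.418) scores belong to mutant-labelled library 1.

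The 3 lists that fell in vesicles rested on mutant-labelled library 1. Ribosomal protein transcripts had a median of -0.42 with 8 of 73 above 0 (camera adjusted p = 3.87e-04, and adjusted p = 0.926 with an estimated correlation). The groups did not overlap in 2 of the 73, where chance gives 13.3% for a single gene and 19.8% of all vesicle genes did so. Rps21 stood at 13.9 RPKM in library 1, 321 in library 2 and 246 to 391 in wild type, and Rpl36 at 92.2 and 322 against 328 to 670. Histone genes had a median of -1.12 with 7 of 35 above 0 (camera adjusted p = 0.00461, and adjusted p = 0.701 with an estimated correlation). The linker histone Hist1h1c stood at 0 and 0.382 RPKM against 6.40 to 12.5, and Hist1h2bc at 2.34 and 76.99 against 58.2 to 96.5. Smooth muscle genes had a median of -1.45 with 1 of 12 above 0 (camera adjusted p = 0.0116, and adjusted p = 0.701 with an estimated correlation). Their myosin Myh11 stood at 0.778 and 47.8 RPKM against 29.9 to 79.9, and Tagln at 27.1 and 329 against 162 to 418. Adjusted over the list alone 0 members passed in these 3 lists. The exact permutation p was 0.4 for ribosomal proteins, 0.133 for histones and 0.2 for smooth muscle. Without mutant-labelled library 1 all 3 calls ended, with an adjusted p of 0.660 for ribosomal proteins (median -0.03), 0.527 for histones (-0.20) and 0.924 for smooth muscle (0.16). The medians were -0.88, -2.29 and -3.10 without mutant-labelled library 2. The ribosomal call also ended without wild-type library 1 (0.101, median -0.28) and with the replicate number as a block, and its median was -0.68 without wild-type library 2. The histone call ended by voom (0.128), and the histone median was -2.11 with a pseudocount of 0.1.

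Neither fibroblast list passed in vesicles (camera adjusted p = 0.252 for adventitial and 0.758 for alveolar fibroblasts), but single genes differed widely in mutant-labelled library 1. Decorin (Dcn), a matrix proteoglycan, stood at 0.550 RPKM in it against 311 in library 2 and 164 to 357 in wild type. The BMP antagonist Grem1 stood at 735 RPKM in it against 6067 and 2573 to 6762. The elastic fibre gene Mfap4 was low in both, at 0 and 11.0 RPKM against 46.3 to 58.1, and fibronectin (Fn1) was above the wild-type range in both, at 162 and 99.0 against 43.5 to 74.2.

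Of the 8096 genes listed in vesicles, 367 had a mean of 0 in the mutant-labelled libraries and 72 in the wild-type ones. The mutant-labelled libraries were fewer and held fewer reads. Among the vesicle genes with the smallest p, several were listed at 0 in both mutant-labelled libraries. These were the respiratory chain gene Ndufa2 (19.4 to 51.0 RPKM in wild type, 55 to 136 reads), Mien1 (18.5 to 28.4), dermatopontin (Dpt, 12.6 to 28.3) and Fkbp7 (7.22 to 30.6). Another respiratory chain gene, Ndufa12, stood at 0.859 and 1.79 RPKM against 22.0 to 66.1. The monocyte chemokine Ccl2 (ENSMUSG00000035385, chromosome 11, 81849073 to 81850955) stood at 17.6 ± 6.33 RPKM against 113 ± 22.9 (-2.64, SE 0.55, 95% interval -3.83 to -1.45), on 26 and 42 reads against 392 to 736. Cfap36 (10.1 against 88.9 RPKM) and Morn4 (0 and 0.329 against 10.6 to 81.7) were the other lower genes. Higher were Cdpf1 (31.9 against 0.206 RPKM), the sorting nexin Snx1 (51.0 against 1.32), Atp6v0b (160 against 11.3), Slc27a1 (36.5 against 1.01), Fut11 (16.3 against 0.145), Fat4 and Arl4c (26.7 against 0.643). Neuropeptide Y (Npy) stood at 56.7 and 11.6 RPKM, on 56 and 11 reads, and was listed at 0 in all wild-type libraries. None of these passed by limma-trend, with an adjusted p of 0.229 to 0.359. The oxidative phosphorylation list had an adjusted p of 0.144, with 1 lower member passing adjusted over the list alone. By exact permutation the growth hormone and IGF list and the FGF signalling list reached p = 0.0667, the smallest possible. Camera did not call them (adjusted p = 0.665 and 0.252).

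Wild-type vesicles ranked many single transcripts far from their place in whole lung, and listed few transcripts of lung epithelium and endothelium. The tables were normalized separately, so levels were set side by side as percentiles within each library without a test. No library holds RNA of the cultured cells themselves. Cell type, culture and loading of vesicles therefore cannot be told apart, in the ranks or in which genes were listed. Grem1 stood at 4919 RPKM in vesicles and 1.59 in lung, the 99.9th against the 6.9th percentile of the 8096 genes shared. The peptide hormone gene Cck stood at 1276 against 0.0165 RPKM. The other genes among the 12 that gained most in rank at a mean log2 level of at least 5 were Znhit6 (234 against 5.10 RPKM), Medag (169 against 5.21), the protease inhibitor Timp1 (173 against 6.79), Hscb, Zeb2, Map1b, Fxr1, Zak, Samd4 and Nop14. Among members of the fixed lists below that level, the activin subunit Inhba stood at 258 against 0.719 RPKM, Ccl2 at 113 against 0.914 and the Wnt agonist Rspo3 at 95.3 against 1.10. They gained more percentile points (94.5, 91.2 and 88.8) than Znhit6 (73). The growth factor genes Igf1, at 49.8 against 2.32 RPKM (percentile 89.1 against 10.2), and Fgf2, at 61.7 against 6.23 (91.1 against 30.1), ranked higher in vesicles, but their lists went both ways. Without overlap of ranks, the growth hormone and IGF list had 7 genes higher in vesicles and 6 higher in lung, of 16 listed. FGF signalling had 3 and 3 of 10, and TGF-beta and BMP signalling 4 and 10 of 17. The IGF-binding proteins Igfbp6 (3.21 against 142 RPKM) and Igfbp4 (2.78 against 49.4) ranked lower in vesicles. So did the endothelial factor Epas1 (2.01 against 581 RPKM, percentile 31.8 against 99.6), the fatty acid transporter Cd36 (3.56 against 300.4), thrombomodulin (Thbd, 8.22 against 164), Bmp6 (0.707 against 46.1) and Pdgfra (2.25 against 36.3). Smad6 was listed at 0 in the wild-type vesicles and stood at 54.7 RPKM in lung. Of the 8096 shared genes, the ranks of the 4 vesicle and 4 lung libraries did not overlap for 2291 higher in vesicles and 1909 higher in lung. Chance gives 2.9% of genes. Ranks without overlap were thus common among all genes, and the list counts above are to be read against that. The wild-type means correlated at 0.511 (Spearman, across genes, which are not independent replicates).

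**Figure D4:**
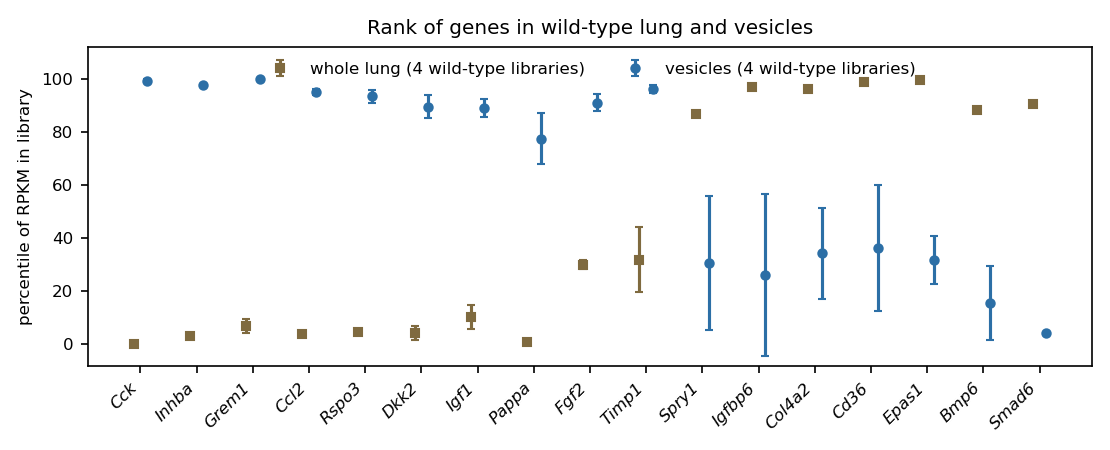
Percentile of RPKM within each library for named genes, as the mean ± SD over 4 wild-type lung libraries (squares) and 4 wild-type vesicle libraries (circles). Genes such as Cck (99.3 against 0.3) and Inhba (97.6 against 3.1) rank high in vesicles and low in lung, while Epas1 (31.8 against 99.6) ranks the other way.

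Of 13463 genes at 1 RPKM or more in wild-type lung, 5699 were not listed in vesicles. Among them were the club cell gene Scgb1a1 (51190 RPKM), the surfactant genes Sftpc (11770) and Sftpb (1694), Cbr2 (2664) and the type 1 cell receptor gene Ager (888). Coverage of the fixed lists varied. Vesicles listed 12 of 14 smooth muscle genes, 23 of 27 matrix genes, 73 of 76 ribosomal protein genes and all 25 genes of oxidative phosphorylation. Of the other mesenchymal lists they listed 8 of 16 alveolar fibroblast genes, 7 of 14 adventitial fibroblast genes and 2 of 11 pericyte genes. They listed 4 of 16 type 2 cell genes, 4 of 16 type 1 cell genes, 1 of 15 endothelial genes, 1 of 14 club cell genes and 0 of 11 B cell genes. Over the members listed in vesicles, 36 of 68 histone genes had a median percentile of 55.1 in vesicles against 9.1 in lung, and 13 of 20 cell cycle genes 42.6 against 6.6. Listed genes had a larger group mean of at least 2.003 RPKM in vesicles, and members not listed do not enter these medians or the counts of ranks.

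The differences of mutant-labelled from wild type were set side by side in lung and vesicles. Over 7413 genes tested in both, the log2 differences correlated at 0.035 (Spearman, across genes), and 50.3% had the same sign. Ribosomal protein transcripts were higher as a list in the mutant-labelled lungs and lower in the mutant-labelled vesicles, and smooth muscle genes were lower in both by camera with a preset correlation. With an estimated correlation the adjusted p was 0.963 and 0.926 for ribosomal proteins and 0.963 and 0.701 for smooth muscle, and without mutant-labelled vesicle library 1 the vesicle medians were -0.03 and 0.16. Whether the genotype effects differed between lung and vesicles was not tested.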

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

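The rules that picked these values were fixed before the data were examined, and the count of opposite directions over all genes was chosen after the results were seen.

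Chance picks about 1 in 20 groups by the test for a library far from the other 3 of its group (Dixon), and here it picked 8 of 90 in wild-type lung and 4 of 58 in wild-type vesicles. Wild-type lung 1 stood apart in 4 values. Its club cell score was -1.295 against 0.148 to 0.287 in the others, Retnla was 4.954 on the log2(RPKM + 1) scale against 6.315 to 6.473, Pdgfra was 5.439 against 5.119 to 5.164, and the score of T-box and mesenchymal transcription factors was 0.09 against -0.043 to -0.031. Wild-type lung 2 had a ribosomal protein score of -0.123 against -0.02 to 0, and an Rpl36 value of 7.986 against 8.128 to 8.146. Wild-type lung 3 had a macrophage score of 0.454 against -0.267 to -0.205 and a Wnt signalling score of -0.081 against 0.022 to 0.038. In vesicles, wild-type library 2 had a heat shock score of -0.528 against 0.112 to 0.15 and a Slc27a1 value of 2.204 against 0.118 to 0.261. Wild-type vesicle library 3 had an FGF signalling score of 0.179 against 0.303 to 0.316, and wild-type vesicle library 1 an Itgax value of 0.078 against 0 in the others. That Itgax value, 1 of the 4, is a single read, and beside 3 values of 0 any read would have been picked, so it shows no library apart.

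Thbs1 and Rpl36 went opposite ways in lung and vesicles, with every mutant-labelled library outside the wild-type range on that side. Over all 7413 genes tested in both, 78 (1.05%) did so, where chance gives 0.89%, so such genes were about as frequent as by chance. Thbs1 differed by -0.235 in lung and 0.874 in vesicles, where it stood at 83.3 and 75.6 RPKM against 28.4 to 66.4. Without wild-type lung 3 its lung difference was -0.15. Rpl36 differed by 0.16 in lung and -1.421 in vesicles, where it was -0.52 without mutant-labelled library 1 and -2.32 without library 2. Neither difference between lung and vesicles was tested. Rpl36 in lung and Thbs1 in vesicles fell outside the rule for named genes and were chosen after their values were seen, and Rpl36 may share reads with near-identical processed copies, while its list had a median of -0.03 in vesicles without mutant-labelled library 1.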

How the results depend on the processing

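Sex and the erythroid score as covariates, wild-type libraries without Y-linked transcripts alone, median-ratio scaling, voom, array weights, thinning and the filter of 1 library were chosen after the data were seen; the other alternatives were planned. Planned tests that need counts (negative binomial tests, count scalings, voom on deposited counts, 1 fit of all 12 libraries, and tests of vesicles against lung and of the interaction) were not run, because the values are RPKM. Of the values outside the main results, 1877 stayed within the bounds set for their kind, 74 weakened, 39 strengthened, 28 moved and 42 reversed. Among the 1877, 991 in lung and 580 in vesicles are gene differences that kept their sign and stayed uncalled, whatever their size. Those genes passed no test in the main fit and could not weaken, so the total is no measure of stability.

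Genes called in lung were 0 in every alternative but that without a filter, which called 1 (Gm17374, chosen after its values were seen: 0.224 and 0.227 RPKM against 0; adjusted p = 0.00907). Lung lists called, 12 in the main test, were 19 with the replicate number as a block, 9 to 18 leaving out each library (19 without mutant-labelled lung 1 at a filter of 1 library), and 0 with an estimated correlation or fry. The neutrophil adjusted p ran from 7.63e-20 to 3.50e-06 leaving out each library, and was at most 5.76e-14 in other camera fits, 0.760 with an estimated correlation and 0.217 by fry. Genes called in vesicles were 0 to 377 leaving out each library (without mutant-labelled library 2, 87 higher and 290 lower, but 206 higher and 165 lower of 371 at a filter of 1 library), 1 by voom and 0 otherwise. Vesicle lists called, 4 in the main test, were 2 to 5 leaving out each library (2 without mutant-labelled library 1, or 0 at a filter of 1 library), 3 with the block, 3 by voom, and 0 with an estimated correlation or fry. The macrophage adjusted p ran from 9.07e-07 to 0.0229 leaving out each library (0.0981 without mutant-labelled library 1 at a filter of 1 library), from 1.14e-07 to 0.00111 in other camera fits, and was 0.701 with an estimated correlation and 0.481 by fry. The correlation of wild-type vesicles with lung, 0.511, was 0.488 to 0.511 leaving out each library (0.488 without wild-type vesicle library 3). An estimated correlation and fry are built otherwise than the preset camera test; for the rest the cause was not tested.

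Leaving out each library reversed some values. Adjusted p for lung lists then ran from 3.50e-06 to 0.174 (type 1 cells), 7.86e-06 to 0.127 (alveolar fibroblasts), 1.38e-06 to 0.240 (matrix), 6.98e-05 to 0.532 (interferon) and 7.28e-07 to 0.825 (mitochondrial), and for vesicle smooth muscle from 9.22e-05 to 0.924. The reversed values at a filter of 1 library were 0.183, 0.0311, 0.252, 0.568, 0.824 and 0.961 in the same order. In lung the log2 difference ran from -0.44 to 0.35 for Tbx4, -0.34 to 0.02 for Ghr, -0.26 to 0.10 for Col1a1, -0.22 to 0.21 for Col1a2 (0.001 with array weights) and -0.74 to 0.17 for Pdgfra. In vesicles it ran from -0.51 to 0.76 for Col1a1 (-0.20 with the block), -0.71 to 1.23 for Col1a2, -7.29 to 0.37 for Dcn, -2.66 to 0.39 for Grem1, -4.50 to 0.043 for Hist1h2bc, -4.69 to 0.085 for Myh11, -4.40 to 0.033 for Rps21 and -3.39 to 0.16 for Tagln. The gene values were the same at a filter of 1 library, and both ends of most ranges rest on the lone mutant-labelled library left. Of the named genes, 19 of 51 in lung and 12 of 34 in vesicles turned or moved by over 1.5 times without some library.

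Genes at an unadjusted p under 0.05 were 514 in lung but 830 without a filter, 292 at a filter of 5 RPKM, 299 against wild-type lungs without Y-linked transcripts, 188 with array weights, and 332 to 2468 leaving out each library. In vesicles they were 781 but 465 against the wild-type libraries without Y-linked transcripts, 362 with array weights, 355 with the block, and 440 to 1758 leaving out each library. The block ended the lung calls of interferon (0.609) and alveolar fibroblasts (0.163) and the vesicle call of ribosomal proteins (0.0580).

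Whether the replicate numbers pair the libraries was not settled. Deviations of same-numbered mutant-labelled and wild-type libraries from their group means correlated at -0.481 and 0.049 in lung and -0.048 and -0.118 in vesicles. With 2 mutant-labelled libraries these deviations mirror each other, so they cannot exclude a pairing. Wild-type lungs and vesicles of the same number correlated at 0.075, -0.062, 0.097 and 0.074. Vesicle libraries agreed poorly among themselves, so these low values do not exclude a shared animal. Wild-type replicates 1 and 2 carried Y-linked transcripts in both sources. No paired test of vesicles against lung was run, since their tables were normalized separately and ranks were compared without a test. Depth limits low vesicle values: 1 read per kilobase was worth 0.573 and 0.596 RPKM in the mutant-labelled libraries against 0.185 to 0.238 in wild type. In simulated vesicle data, whose spread was taken from the wild-type libraries alone, 0% of 2-fold changes were called.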

Other observations

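The tests of sex, of blood and of mutant-labelled library 1 alone, the second macrophage list and all genes of the next paragraph were chosen after the results were seen. The predictions for scaling, depth and few molecules were written before their own results. Median-ratio scaling and thinning themselves were chosen after the data were seen.

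Lung libraries also differed in a way that crossed the genotype labels. Gpnmb, Ctsk and Mmp12 are given because they were among the genes leading the split described next, so their values only illustrate it. The glycoprotein Gpnmb stood at 21.4 RPKM in mutant-labelled lung 1 and 24.9 in wild-type lung 3, against 3.36 to 4.36 in the other lungs. Cathepsin K (Ctsk) stood at 51.5 and 57.5 RPKM against 9.58 to 12.5, and the macrophage elastase Mmp12 at 11.9 and 15.2 against 1.38 to 2.31. Of the 15 ways to set 2 lungs against the other 4, this pair gave the most genes by limma, 72, while the labelled split gave 0 (514 at an unadjusted p under 0.05; voom 0), which points to a structure of the samples other than the labels. Wild-type lungs 1 and 2 against the rest gave 5 genes, led by Ddx3y and Eif2s3y. In vesicles the labelled split gave 0 (781 unadjusted; voom 1) and the highest other split 19, for wild-type libraries 1 and 4, with Spp1, Lyz2, Fcer1g and Ctss leading. With 15 splits a share under 0.05 cannot be reached.

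Neutrophil genes were higher in both mutant-labelled lungs. Sex as the whole cause is argued against, since against the wild-type lungs without Y-linked transcripts the median difference was 1.28 (quartiles 0.84 to 2.03, camera adjusted p = 6.54e-16, within a range over alternatives of 1.75e-23 to 0.760). Scaling is argued against by a median of 1.53 after median-ratio scaling, whose factors ran only from 0.993 to 1.014 over the lungs. Blood left in the tissue is argued against as the whole cause, as far as erythroid genes follow it: with the erythroid score as a covariate the median was 1.27 (quartiles 0.67 to 1.77, camera adjusted p = 4.10e-15), although 1 of the 2 mutant-labelled lungs had an erythroid score above every wild-type lung (0.783 against 0.771). Neutrophil number was not measured, so more cells and more RNA per cell were not separated. Genotype as the reason was not tested, since only 2 lungs carry the label and the sources name different floxed genes. Whole-gene Tbx4 reads, which were not lower in mutant-labelled lung 2, do not settle the genotype.

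Vesicle libraries of one group agreed poorly. Sequencing depth is argued against as the whole cause: wild-type lungs thinned to the reads of the shallowest vesicle library still correlated at 0.97 to 0.979. For mutant-labelled library 1, the lowest wild-type pair lay 0.15 above its highest correlation with a wild-type library (0.582 against 0.433) after thinning to equal reads. Few starting molecules may contribute and stay open: 3.5% of genes with at least 30 reads in 1 wild-type vesicle library had 0 in another, between the bounds of 1% and 5% set in advance, against 0.008% in lung. No biological explanation was tested.

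Macrophage genes were higher in the mutant-labelled vesicles, and RNA of macrophages carried along in the mesenchymal cultures is a candidate source that stays open. A second list of 20 macrophage genes, of which wild-type lung expresses 20 at 1 RPKM or more and another fixed list holds 1, had a median difference of 2.76 with 18 of 18 tested genes above 0, but it was chosen after the pattern was seen and holds Spp1, Fcer1g and Ctss, which lead the split of wild-type libraries 1 and 4, so it could have spoken against this source and cannot speak for it. Its scores were 2.51 and 1.17 against -2.42, 0.93, 0.64 and -2.83. Among its most abundant genes Spp1 stood at 8633 and 3648 RPKM against 115, 2480, 3110 and 24.9, and Ctsd at 801 and 816 against 81.5 to 725. After thinning to equal reads the median was 2.44. Thinning keeps the expected RPKM of a gene, so a large fall was unlikely in advance and the value says little about depth. Without mutant-labelled library 1 the median was 2.57 (quartiles 1.69 to 3.11, adjusted p = 0.0229, in a range of 1.14e-07 to 0.701 over all alternatives), against 2.44 (1.76 to 3.43) with it, which speaks against library 1 as the only carrier. With a filter of 1 library the median was 2.28 (1.31 to 3.08) and the call was lost (adjusted p = 0.0981) after genes read in 1 library had joined those tested, which does not speak for library 1 alone. That explanation stays open only because library 2 is then a single library, with a score of 1.396 on the first list against -2.631 to 1.119 in wild type. The scores of wild-type libraries 2 and 3 lay nearer to the mutant-labelled ones than to those of wild-type libraries 1 and 4, so a difference between cultures rather than genotypes cannot be set aside, and no genotype effect was tested apart from it.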
